A study of Mus musculus with 8 samples.

How the data were processed

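Microglia were sorted from the hippocampus of C57/Bl6 mice at postnatal day 30, 4 hours after an injection of interleukin-33 (IL-33) or of phosphate-buffered saline (PBS). Per the labels' protocols the mice were perfused with PBS, the dissected hippocampi were homogenised mechanically, and cells were taken by flow cytometry as CD45 low, CD11b positive and Ly-6C negative. Libraries were made with the Lexogen QuantSeq FWD kit, which reads the 3′ end of polyadenylated transcripts, so that a value counts fragments from transcript ends and does not scale with gene length. There were 8 libraries, 4 after IL-33 (replicates 1 to 4) and 4 after PBS (replicates 5 to 8), with 2 females and 2 males in each group, all taken from the labels. The labels name the libraries as separate samples and do not say whether each came from its own animal, so that p-values measure the spread between these samples, which may be partly technical.

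The deposited table holds a signal for each gene and library. It is named as normalized counts, and whole reads recovered from the deposited values show that they are read counts divided by 1 factor per library: in each library 100% of the values above 0 were whole multiples of the value of 1 read, within a tolerance of 0.01 read. The submitters' processing notes name FastQC, STAR 2.5.4b, HTSeq 0.9.0, DESeq2 1.24.0 and the mouse builds mm10 and GRCm38, without saying what each was used for. Whether the counting used the strand, how reads matching several places were treated and whether duplicates were removed are not given in the sources used here. QuantSeq libraries without molecular identifiers can hold many copies of 1 starting molecule, and genes found in a single library with at least 30 reads had a median of 80 to 208 reads there, depending on the library. Reads are therefore not independent molecules, and the limit that a count of 0 allows, 3 counts, covers counting error alone. On the deposited scale that limit lay between 2.20 and 3.12 per library.

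Dividing by the value of 1 read gave back the read numbers, from 16.83 M to 21.48 M per library. The table had 55471 rows, of which 55230 had an Ensembl identifier in GENCODE release M21 of the mouse genome GRCm38, from which coordinates were taken. No reads were present for 36850 genes, and 305 symbols stood on more than 1 row; in gene lists the row with the highest mean was used. All columns belonged to the 8 libraries.

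The comparison of IL-33 with PBS used limma 3.58.1 in R 4.3.3 on log2(value + 1), with a moderated test that lets the variance follow the expression level, group as the sole term and a two-sided test. Genes with a mean of at least 10 over the 8 libraries were tested, 13877 in all, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are differences between the group means of log2(value + 1). The added 1 understates the change of genes with few reads. A single library far below the others of its group can also move this difference away from the ratio of the group means. Examples are H2-DMb1 (−3.72 here and −2.41 in edgeR) and Il1rap (1.06 and 1.81). The difference of the IL-33 effect between females and males was tested as an interaction in a model with a mean for each treatment and sex, and counts within each sex came from the same model. Males and females were compared in a model with sex and treatment. The 33 gene lists, with 975 entries, were tested with camera from limma at a preset correlation of 0.01 between genes. P-values were adjusted over the 32 lists with at least 5 tested members. Camera compares a list with all other tested genes, so that its direction is relative to them.

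Named genes followed a rule: the IL-33 receptor genes Il1rl1 and Il1rap; the 12 largest rises and 12 largest falls among called genes whose groups did not overlap and that carry an established symbol; for each list up to 4 called members with the largest change, or 2 abundant members where none was called; 2 abundant members of each list of another cell type; and up to 3 called genes in each direction between the sexes and up to 5 for the interaction. Further genes were chosen after their values were seen, and the text says so where it names them. Values of some genes that the rule names are not reported here. The samples' groups, the tests, the rule, the gene lists and most alternatives were fixed before the data were examined.

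The alternatives were pseudocounts of 0.5 and 5, no filter on low values, a minimum mean of 50, TMM scaling, quantile normalization, no variance trend, weights for each library, sex as a covariate, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, leaving out each library in turn, an adjusted p under 0.01, an absolute log2 fold change over 1, camera with an estimated correlation, and fry. Added after the data were seen were a pseudocount of 100, a minimum mean of 1000, a fit without the 2 libraries with the fewest genes, and camera with a variance trend, since the trend setting of the gene test does not enter camera.

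The tests were checked on simulated counts drawn from the PBS means and the spreads of the 13877 genes, with 200 changed genes in each of 10 simulations. In this paragraph a gene's mean is its PBS mean, not the mean over the 8 libraries used elsewhere. For the treatment comparison, genes with a mean of at least 1000 were recovered in 2% of cases at a 2-fold change, 32.4% at 4-fold, 80% at 16-fold and 91.1% at 64-fold, and genes below that level in 0%, 0.5%, 10.4% and 20.1%. Of the simulated treatment calls, 2.68% were false. For the interaction, a 64-fold difference was recovered in 19.4% of cases at a mean of at least 1000 and in 0.5% below it. For the sex comparison, a 16-fold difference was recovered in 69.4% and 4.4%. A list of 30 genes raised 16-fold was called in 10 of 10 simulations and a list of 30 unchanged genes in 0 of 10. Simulated genes varied independently of each other, so that these list results do not check the preset correlation for genes that vary together.

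Of the 148 named genes, 46 share annotated exon positions with another gene, 10 of them on the same strand, where the partners are short RNAs or transcripts with no reads. Since no source used here states a strand setting, reads of the others cannot be told apart from those of the partner on the opposite strand. Values of genes with near-identical copies (Bcl2a1d, H2-Q7, H2-K1, Ifitm3 and ribosomal protein genes with processed pseudogenes) are uncertain for the same kind of reason.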

Results

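RNA was sequenced from microglia, the resident macrophages of the brain, sorted from the mouse hippocampus 4 hours after injection of the cytokine IL-33 (4 libraries) or of PBS (4 libraries). The series title places the experiment in a study of how microglia remodel the extracellular matrix. The libraries held 16827343 to 21483352 reads assigned to genes. Their means were 18.88 ± 1.69 M reads after IL-33 and 19.97 ± 1.03 M reads after PBS (SD, n = 4 each; exact permutation p = 0.314, two-sided). Genes with at least 10 reads numbered 10736, 10432, 8948 and 7958 in IL-33 replicates 1 to 4, and 10950, 10311, 11902 and 10905 in PBS replicates 5 to 8. The means were 9519 ± 1301 and 11017 ± 658 (SD, n = 4 each; exact permutation p = 0.086, where 0.029 is the smallest possible). The mean Pearson r across genes was 0.705 between IL-33 libraries, 0.715 between PBS libraries and 0.639 between the groups. All values below are normalised read counts as mean ± SD with n = 4 per group, and adjusted p-values are from limma unless another tool is named. Fold changes are the mean log2(value + 1) after IL-33 minus that after PBS. They need not equal the log2 ratio of the printed means.

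The first comparison asked how microglial gene expression differed 4 hours after IL-33 from that after PBS. Inflammatory transcripts that were low after PBS rose many-fold after IL-33, while many genes that mark resting microglia fell. Il1b, which encodes the cytokine interleukin-1β, rose from 190 ± 21 to 93365 ± 23250 (log2 fold change 8.90 ± 0.30 SE, adjusted p = 3.34e-13). Il12b, a subunit of interleukin-12 and interleukin-23, rose from 192 ± 11.7 to 95219 ± 52820 (8.81, adjusted p = 1.97e-12). The purinergic receptor gene P2ry12, chosen after its values were seen, fell from 71702 ± 19600 to 13030 ± 4520 (−2.47, adjusted p = 7.01e-07). The receptor gene Gpr34 fell from 17389 ± 1669 to 533 ± 190 (−5.10, adjusted p = 1.23e-08). Not all abundant microglial genes moved: Cx3cr1, the fractalkine receptor, also chosen after its values were seen, was at 198000 ± 51970 after IL-33 and 195360 ± 46100 after PBS (0.01 ± 0.16 SE, adjusted p = 0.9779).

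In all, 812 of the 13877 tested genes passed the threshold, 424 higher and 388 lower after IL-33, and 2698 had an unadjusted p under 0.05. In 791 of the 812 the 4 IL-33 values and the 4 PBS values did not overlap. Among all tested genes 1897 (13.7%) did not overlap, where chance gives 2.86%. The median fold change of all tested genes was −0.40, against 0.08 for the 3116 genes with a mean of at least 1000, which held 601 of the calls (341 higher, 260 lower). Quantile normalization moved the median of all genes by 0.29, and leaving out IL-33 replicates 3 and 4 moved it by 0.28. edgeR on the recovered reads called 757 genes (439 higher, 318 lower), 696 of them shared with limma in the same direction, while limma without a variance trend called 413 (175 higher, 238 lower) and DESeq2 called 1647 (784 higher, 863 lower). Without PBS replicate 5, 6, 7 or 8 the calls numbered 516, 458, 505 and 486, of which 185, 153, 176 and 173 were lower. IL-33 replicates 3 and 4, both male, had the fewest genes of all libraries, and a fit without this pair called 285 genes higher and 473 lower.

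**Figure D1:**
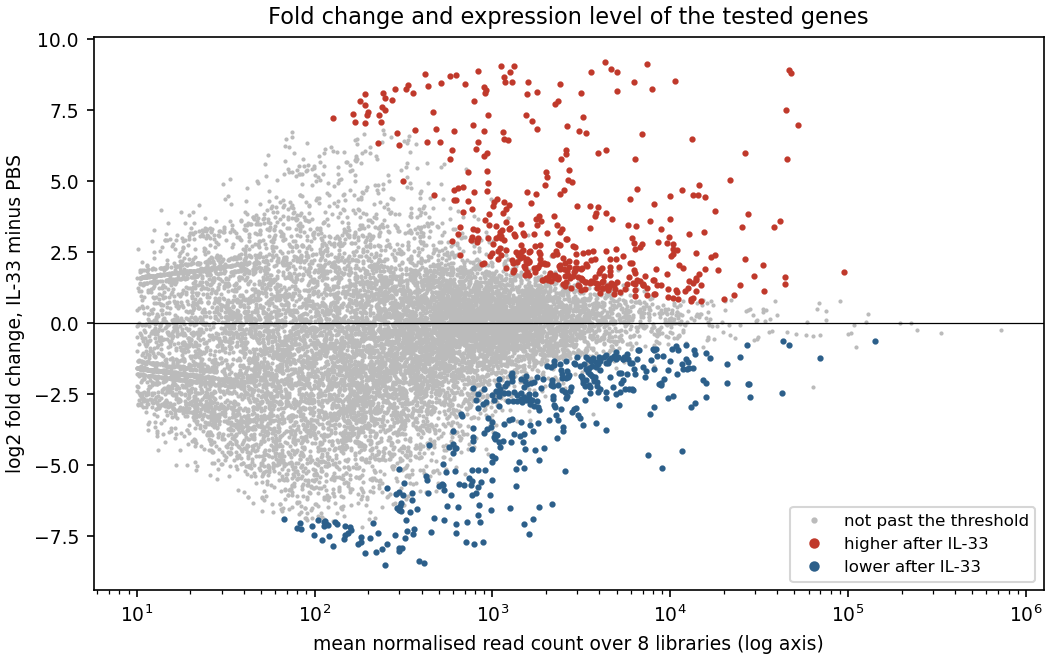
Each point is one of the 13877 tested genes, with its mean normalised read count over the 8 libraries on a logarithmic horizontal axis and its log2 fold change (IL-33 minus PBS) on the vertical axis. The 424 genes called higher are red and the 388 called lower are blue; 601 of these 812 calls have a mean of at least 1000, and the rises end near a log2 fold change of 9.20.

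The 12 largest rises among genes whose groups did not overlap were Il1rn, Marco, Cx3cl1, Cxcl2, Ccl22, Il1b, Gas7, Zfp811, Itgal, Ccr7, Il12b and Ptprf, with log2 fold changes of 8.77 to 9.20. The chemokine gene Ccl22 went from 17.2 ± 3.28 to 9256 ± 2328 (8.97, adjusted p = 8.31e-08), and Ccr7, a chemokine receptor, from 20.7 ± 2.37 to 10028 ± 1960 (8.84, adjusted p = 4.04e-08). The scavenger receptor Marco went from 24.6 ± 2.04 to 14711 ± 3419 (9.14, adjusted p = 6.01e-09). The PBS means of these 12 genes were 0.094% to 0.207% of their IL-33 means, and Xist, which is transcribed from the inactive X chromosome of females, was present in male libraries at 0.293% of its female mean.

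The 12 largest falls were Rnase6, Hbegf, Marveld2, Sgsh, Nudt7, Pik3ip1, Kitl, Calcrl, Lmln, Gpr155, Mir8110 and Etv1, with log2 fold changes of −8.53 to −7.70. Mir8110 is annotated as a microRNA on chromosome 8 (89024735 to 89024831), near Sall1 on the opposite strand (89027235 to 89044162). Which transcript its reads came from was not tested, so that they do not show a fall of the microRNA itself. Hbegf, a growth factor of the epidermal growth factor family, went from 828 ± 387 to 1.47 ± 1.35 (−8.45, adjusted p = 0.006728), and Gpr155 from 1764 ± 678 to 7.33 ± 2.91 (−7.72, adjusted p = 6.46e-04). Kitl, the ligand of the receptor Kit, had no reads in the 4 IL-33 libraries and 254 ± 107 after PBS. Against a floor of 3 counts per library Kitl was at least 88.4-fold lower after IL-33. That floor covers counting error alone, and reads are not independent molecules, so that the true change may be smaller. For 9 of the 12 (all but Hbegf, Gpr155 and Etv1) leaving out at least 1 PBS library ended the call.

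**Figure D2:**
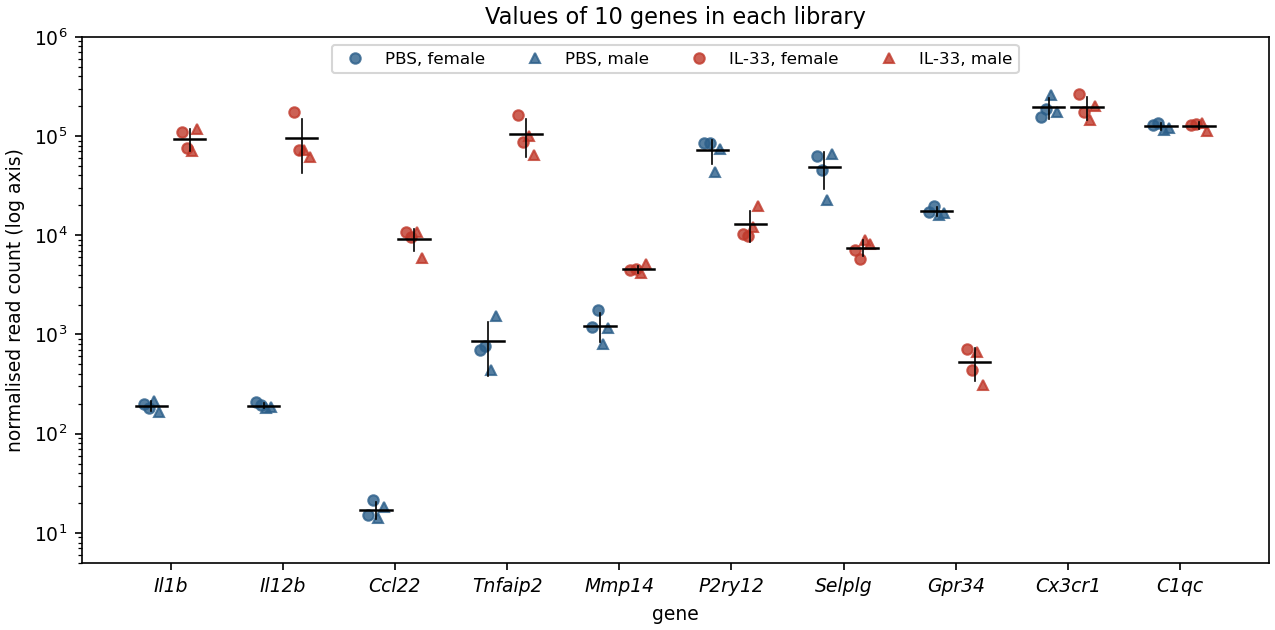
Normalised read counts of 10 genes are shown for each library on a logarithmic axis, PBS in blue and IL-33 in red, with circles for females and triangles for males; horizontal bars are means and vertical lines are ± 1 SD (n = 4). Il1b rises from a mean of 190 to 93365, Gpr34 falls from 17389 to 533, and Cx3cr1 and C1qc lie at like levels in both groups.

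Cytokine and chemokine genes rose together. Of 28 tested members, 18 rose, 0 fell and 10 did not pass (21 up and 1 down adjusted over the list alone; camera adjusted p = 9.99e-29, and adjusted p = 0.002305 with an estimated correlation). Besides Il1b they included Il1rn, the antagonist of the interleukin-1 receptor (13.9 ± 4.94 to 8533 ± 1513, 9.20, adjusted p = 1.52e-07), and Tnf, the tumour necrosis factor gene (56.7 ± 42.6 to 15722 ± 6228, 8.26, adjusted p = 1.62e-08, chosen after its values were seen). Il6, also chosen after its values were seen, was at 6.77 ± 13.5 after PBS and 39.5 ± 48.4 after IL-33 (adjusted p = 0.6243). Leaving out the 2 libraries with the fewest genes (8948 and 7958 genes with at least 10 reads) gave 16 members higher and 0 lower.

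Targets of the transcription factor NF-κB and genes of its feedback also rose: 17 of 24 rose, 0 fell and 7 did not pass (20 up and 0 down adjusted over the list alone; camera adjusted p = 2.96e-22, and adjusted p = 0.003106 with an estimated correlation). Tnfaip2 went from 864 ± 479 to 103760 ± 43050 (6.97, adjusted p = 9.97e-11) and Traf1, an adaptor of tumour necrosis factor receptors, from 4.64 ± 2.45 to 1819 ± 1422 (8.10, adjusted p = 0.001457). The inhibitor gene Nfkbia, chosen after its values were seen, went from 4720 ± 2007 to 46285 ± 3771 (3.38, adjusted p = 1.62e-08). With those 2 libraries left out, 14 members were higher and 0 lower.

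Of the anti-inflammatory feedback genes 7 of 21 rose and 0 fell (8 up and 1 down adjusted over the list alone; camera adjusted p = 4.17e-04, but adjusted p = 0.1052 with an estimated correlation). They included the phosphatase gene Dusp2 (198 ± 160 to 13741 ± 5355, 6.65, adjusted p = 2.75e-06) and Socs3, which inhibits cytokine receptor signalling (260 ± 353 to 8448 ± 6509, 6.08, adjusted p = 2.02e-04). The type I interferon response list rose as a set, with 5 of 34 members higher and 0 lower (6 up and 0 down adjusted over the list alone; camera adjusted p = 7.61e-06, and adjusted p = 0.01584 with an estimated correlation). Gbp2, a guanylate-binding protein, went from 191 ± 73.9 to 4594 ± 2303 (4.56, adjusted p = 4.17e-05) and the ubiquitin-like modifier Isg15 from 195 ± 164 to 1708 ± 362 (3.44, adjusted p = 0.005809). The higher and lower counts without the 2 libraries with the fewest genes were 6 and 0 for feedback genes and 4 and 0 for interferon genes.

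Genes of antigen presentation, pattern recognition, complement and alternative activation rose in part. In antigen presentation 7 of 26 rose and 1 fell (8 up and 1 down adjusted over the list alone; camera adjusted p = 4.73e-04, and adjusted p = 0.02598 with an estimated correlation). The co-stimulatory receptor Cd40 went from 22.9 ± 35.7 to 3107 ± 745 (8.07, adjusted p = 1.29e-04) and Cd74, the invariant chain, from 149 ± 122 to 2335 ± 1158 (4.16, adjusted p = 0.00198). H2-DMb1, which loads class II molecules with peptide, fell from 1581 ± 409 to 294 ± 351 (−3.72, adjusted p = 0.04244), a call that edgeR did not make (adjusted p = 0.1161). In pattern recognition 7 of 23 rose and 1 fell (8 up and 4 down adjusted over the list alone; camera adjusted p = 0.01796, but adjusted p = 0.1157 with an estimated correlation). Tlr2 went from 1369 ± 662 to 42104 ± 10040 (5.04, adjusted p = 2.60e-09) and Tlr1 from 1132 ± 211 to 25865 ± 4250 (4.51, adjusted p = 2.60e-09). With the 2 libraries with the fewest genes left out, 6 antigen presentation genes were higher and 0 lower, and 5 pattern recognition genes higher and 2 lower.

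In the complement list 3 of 13 rose and 0 fell (4 up and 2 down adjusted over the list alone; camera adjusted p = 0.01946, but adjusted p = 0.1052 with an estimated correlation). The 3 were the receptors C3ar1 (6759 ± 1754 to 70170 ± 12360, 3.40, adjusted p = 2.60e-09) and C5ar1 (745 ± 536 to 4480 ± 719, 2.96, adjusted p = 0.002147) and the component C3 (0.96 ± 1.13 to 672 ± 336, 8.39, adjusted p = 0.01168). C1qc, a chain of the initiating complex, was at 126800 ± 10190 after IL-33 and 124860 ± 9832 after PBS (0.02 ± 0.11 SE, adjusted p = 0.9263, chosen after its values were seen). In the type 2 and alternative activation list 5 of 17 rose and 0 fell (5 up and 0 down adjusted over the list alone; camera adjusted p = 0.006329, but adjusted p = 0.1135 with an estimated correlation). They included Ccl22 and the transglutaminase gene Tgm2 (315 ± 235 to 2371 ± 886, 3.07, adjusted p = 0.004064). A fit without the 2 libraries with the fewest genes had 3 complement genes higher and 1 lower, and 3 genes of alternative activation higher and 0 lower.

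Homeostatic microglial genes, which distinguish resting microglia from other macrophages, fell as a set. Of 42 tested members 27 fell, 2 rose and 13 did not pass (33 down and 2 up adjusted over the list alone; camera adjusted p = 3.35e-08, and adjusted p = 0.00777 with an estimated correlation). Pmepa1 fell from 22047 ± 4776 to 1108 ± 613 (−4.49, adjusted p = 2.00e-07). Of members chosen after their values were seen, the transcription factor gene Sall1 fell from 5726 ± 959 to 1287 ± 393 (−2.19, adjusted p = 6.46e-04) and Selplg from 49048 ± 19640 to 7520 ± 1381 (−2.61, adjusted p = 2.61e-06). Tmem119, also so chosen, was at 36012 ± 7798 after PBS and 23443 ± 3063 after IL-33 (−0.60, adjusted p = 0.0517). The 2 that rose were P2ry6 (7004 ± 1757 to 14707 ± 2777, 1.08, adjusted p = 0.01009, chosen after its values were seen) and Gpr84, from 221 ± 69.3 to 12464 ± 4886 (5.78, adjusted p = 5.84e-08). Leaving out the 2 libraries with the fewest genes gave 24 members lower and 1 higher.

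Phagocytic and matrix receptors moved both ways, with 6 of 36 higher and 9 lower (10 up and 14 down adjusted over the list alone; camera adjusted p = 0.5577). Cd44, the receptor of hyaluronan, rose from 86.1 ± 110 to 5166 ± 2266 (6.96, adjusted p = 9.03e-05). Mertk, a receptor for dying cells, fell from 25776 ± 4460 to 5990 ± 1250 (−2.11, adjusted p = 3.19e-06, chosen after its values were seen). The median fold change of this list was −0.47 and its mean 0.47. In the fit without the 2 libraries with the fewest genes 4 members were higher and 8 lower. In the disease-associated microglia list 5 of 33 rose and 3 fell (7 up and 9 down adjusted over the list alone; camera adjusted p = 0.5521, direction up with a median of −0.37 and a mean of −0.09). The lipoprotein lipase gene Lpl rose from 1336 ± 625 to 29910 ± 17070 (4.45, adjusted p = 9.78e-08). In this list 4 members were higher and 3 lower without the 2 libraries with the fewest genes.

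The extracellular matrix is the subject of the series title, and its enzymes and components were described by 3 lists. Summed over each list, reads were fewer after IL-33, as found after the data were seen (exact permutation p = 0.029 for each, the smallest possible). Matrix proteases and inhibitors took 0.248 ± 0.0412% of reads after IL-33 and 0.396 ± 0.0304% after PBS, lysosomal cathepsins and hydrolases 3.63 ± 0.227% and 4.61 ± 0.169%, and matrix components 0.490 ± 0.0293% and 0.704 ± 0.110%. A sum weighs each gene by its abundance. Sparc made up most of the matrix component sum, and Hexa, Timp2 and Serpine2 most of the protease and inhibitor sum after PBS. The sums therefore do not show that members of those lists fell in general. Shares of reads also fall when other genes take more reads. Of 25 tested matrix proteases and inhibitors 3 rose and 3 fell (4 up and 5 down adjusted over the list alone; camera adjusted p = 0.4913, direction up, while fry gave the opposite direction with adjusted p = 0.9144). Mmp14, a membrane-bound collagenase, rose from 1231 ± 399 to 4564 ± 387 (1.94 ± 0.37 SE, adjusted p = 0.002683). Adamts4, which cleaves the proteoglycan aggrecan, rose from 49.7 ± 64.9 to 2265 ± 1655 (6.50, adjusted p = 0.007142). Hexa, a lysosomal hexosaminidase, fell (−1.27, adjusted p = 0.001866), as did Timp2, an inhibitor of metalloproteinases (−0.93, adjusted p = 0.01703), and the protease inhibitor Serpine2 (−1.16, adjusted p = 0.01429), the last 2 chosen after their values were seen. The calls of these 5 genes were lost without the variance trend. In the fit without the 2 libraries with the fewest genes 2 members of the list were higher and 4 lower. Of 33 lysosomal cathepsins and hydrolases 1 rose and 4 fell (2 up and 5 down adjusted over the list alone; camera adjusted p = 0.3936, while fry, which does not compare the list with other genes, gave adjusted p = 3.78e-04 with the direction down). Cathepsin D (Ctsd) fell from 95183 ± 22720 to 44714 ± 22870 (−1.22, adjusted p = 0.01013), and cathepsin C (Ctsc) rose from 7041 ± 1911 to 18211 ± 11270 (adjusted p = 0.02184). Both calls were lost without the 2 libraries with the fewest genes, where 0 members were higher and 4 lower. Hexa belongs to both the lysosomal list and the protease and inhibitor list, and counts in the falls and the read sum of each. Of 13 tested matrix components and perineuronal net proteins limma called 0 (0 adjusted over the list alone; camera adjusted p = 0.9883) and edgeR 1, the proteoglycan gene Vcan. Vcan was at 0.21 ± 0.41 after PBS and 254 ± 188 after IL-33, with 0 in IL-33 replicate 4 (adjusted p = 0.1458 in limma and 0.04761 in edgeR). The most abundant, Sparc, was at 113220 ± 18960 after PBS and 86802 ± 8320 after IL-33 (−0.37, adjusted p = 0.09793).

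**Figure D3:**
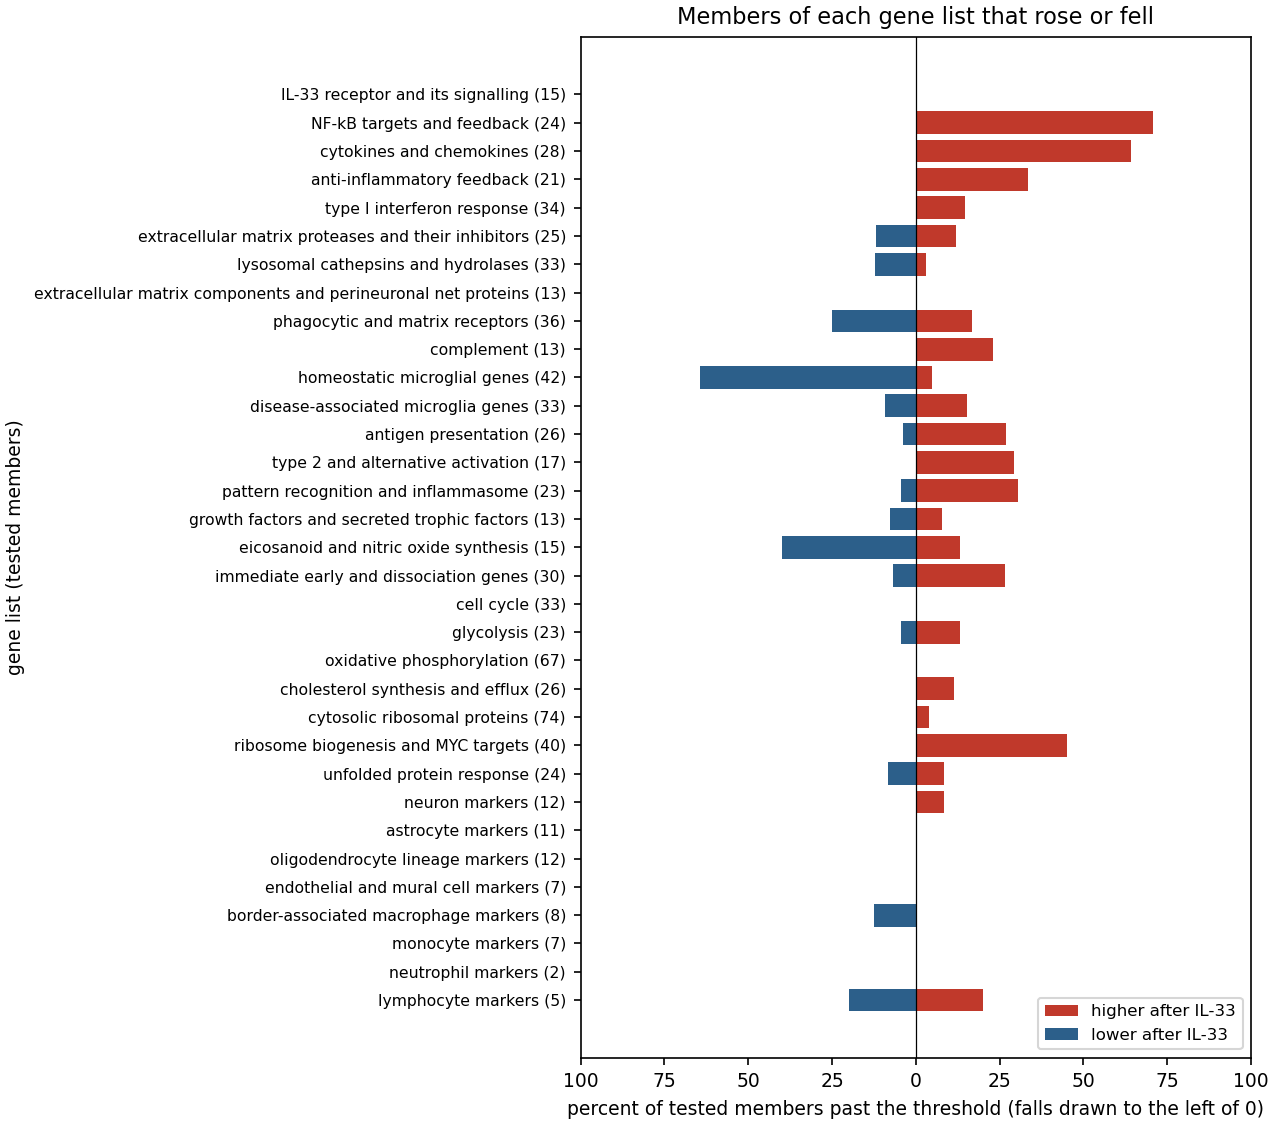
Bars give the percent of tested members of each of the 33 fixed gene lists that were called higher (red, to the right) or lower (blue, to the left) after IL-33, with the number of tested members in brackets. The cytokine list (18 of 28 higher), the NF-κB list (17 of 24 higher) and the homeostatic list (27 of 42 lower) have the longest bars.

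Ribosome biogenesis and MYC target genes rose, 18 of 40 with 0 lower (27 up and 0 down adjusted over the list alone; camera adjusted p = 6.07e-14, and adjusted p = 0.00777 with an estimated correlation). Srm, the spermidine synthase gene, went from 536 ± 352 to 2358 ± 367 (adjusted p = 0.02047). Single libraries mattered here: 5 of the 18 were called in all 8 fits that left out 1 library, and without the 2 libraries with the fewest genes 12 were higher. Cytosolic ribosomal protein genes had 3 of 74 higher and 0 lower (3 up and 0 down adjusted over the list alone; camera adjusted p = 0.005632, but adjusted p = 0.3699 with an estimated correlation). Among them Rps2 went from 4062 ± 865 to 11918 ± 3407 (1.52, adjusted p = 0.002285). Immediate early and dissociation genes had 8 of 30 higher and 2 lower (8 up and 2 down adjusted over the list alone; camera adjusted p = 0.008484, but adjusted p = 0.1052 with an estimated correlation). Junb went from 1894 ± 936 to 10772 ± 2751 (2.61, adjusted p = 1.33e-04). Rgs2, a regulator of G protein signalling, fell from 26994 ± 4873 to 4816 ± 2469 (−2.59, adjusted p = 5.20e-06). The fit without the 2 libraries with the fewest genes had 4 ribosomal protein genes higher and 0 lower, and 7 immediate early genes higher and 1 lower.

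Genes for the synthesis of eicosanoids and nitric oxide moved both ways, with 6 of 15 lower and 2 higher (7 down and 3 up adjusted over the list alone; camera adjusted p = 0.969, direction down with a median of −1.20 and a mean of 0.35). Ptgs1, the constitutive cyclooxygenase, fell from 17844 ± 5538 to 2933 ± 541 (−2.56, adjusted p = 4.62e-06). Ptges, a prostaglandin E synthase, rose from 1.03 ± 0.45 to 865 ± 630 (8.34, adjusted p = 0.01016). The inducible cyclooxygenase Ptgs2, chosen after its values were seen, was at 0.82 ± 1.21 after PBS and 346 ± 503 after IL-33 (adjusted p = 0.08519 in limma and 0.03176 in edgeR). When the 2 libraries with the fewest genes were left out, 6 members were lower and 0 higher, so that the call of Ptges was lost. edgeR called 4 lower and 3 higher, and 2 lower and 2 higher were called in all 8 fits that left out 1 library.

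In glycolysis 3 of 23 rose and 1 fell (3 up and 1 down adjusted over the list alone; camera adjusted p = 0.2635, direction up with a median of 0.27 and a mean of −0.32). Pfkfb3, an activator of phosphofructokinase, went from 1757 ± 664 to 9141 ± 3418 (2.37, adjusted p = 2.81e-04). In the unfolded protein response 2 of 24 rose and 2 fell (2 up and 2 down adjusted over the list alone; camera adjusted p = 0.1298, while fry gave adjusted p = 0.04424 with the direction up). edgeR called 2 higher and 0 lower. Herpud1 went from 3057 ± 781 to 28000 ± 5742 (3.21, adjusted p = 4.13e-08). Cholesterol synthesis and efflux had 3 of 26 higher and 0 lower (3 up and 0 down adjusted over the list alone; camera adjusted p = 0.2991). Among them was Ch25h, the cholesterol hydroxylase (11.9 ± 3.66 to 6252 ± 6547, 8.10, adjusted p = 1.18e-04). Growth and trophic factors had 1 of 13 higher, Igfbp4 (661 ± 81.8 to 8725 ± 2989, 3.66, adjusted p = 2.61e-06), and 1 lower, Hbegf (1 up and 1 down adjusted over the list alone; camera adjusted p = 0.9277, direction up with a negative median and mean). In limma 0 of 67 genes of oxidative phosphorylation passed (0 adjusted over the list alone; camera adjusted p = 0.5577, direction up with a negative median and mean). Of 33 cell cycle genes, limma likewise called 0 (0 adjusted over the list alone; camera adjusted p = 0.2002). Counts of higher and lower genes without the 2 libraries with the fewest genes were 1 and 1 for glycolysis, 2 and 1 for the unfolded protein response, 1 and 0 for cholesterol genes and 1 and 1 for growth factors.

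The IL-33 receptor and its signalling genes were not called: 0 of 15 passed (1 up and 0 down adjusted over the list alone; camera adjusted p = 0.2461). Il1rl1, the IL-33 receptor chain ST2, was at 216 ± 171 after PBS and 22.9 ± 43.3 after IL-33, with overlapping groups (−4.78 ± 2.10 SE, adjusted p = 0.2122), and the co-receptor gene Il1rap at 74.3 ± 65.5 and 255 ± 194 (1.06 ± 2.16 SE, adjusted p = 0.8044). The kinase gene Irak2 was at 1389 ± 317 after PBS and 3923 ± 1554 after IL-33 (1.42, adjusted p = 0.05005), and edgeR called it higher (adjusted p = 0.02522). In the fit without the 2 libraries with the fewest genes 1 member of the list was higher and 0 lower.

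Markers of other cells that a brain dissection can hold were mostly not called one by one, but the summed reads of some lists differed between the groups, as found after the data were seen. Neuron markers took 0.0278 ± 0.00834% of reads after IL-33 and 0.0129 ± 0.00339% after PBS (exact permutation p = 0.029, the smallest possible), and border-associated macrophage markers 0.0168 ± 0.00199% and 0.0426 ± 0.0119% (exact permutation p = 0.029). Astrocyte markers took 0.0433 ± 0.0119% and 0.0280 ± 0.00527% (exact permutation p = 0.057), with a median log2 fold change of 1.96, and endothelial and mural markers 0.00209 ± 0.000845% and 0.00476 ± 0.00227% (exact permutation p = 0.057). Monocyte markers took 0.00356 ± 0.00225% and 0.000841 ± 0.000499% (exact permutation p = 0.086). Some of these sums rest largely on single genes. Prox1 made up most of the neuron difference, Stab1 most of the border-associated macrophage sum and Slc1a3 most of the astrocyte sum. The sums of those lists do not show by themselves that their markers moved together. Among neuron markers 1 of 12 rose, Prox1, a transcription factor of dentate granule cells (573 ± 272 to 2559 ± 738, 2.25, adjusted p = 0.01168), and 0 fell (1 up and 0 down adjusted over the list alone; camera adjusted p = 0.06392). Of 11 astrocyte, 12 oligodendrocyte, 7 endothelial and mural and 7 monocyte markers limma called 0, also adjusted over each list alone (camera adjusted p = 0.06392, 0.9883, 0.5577 and 0.1291). edgeR called 1 of the monocyte markers higher, Vcan (adjusted p = 0.04761). The oligodendrocyte list had a negative median and mean with the camera direction up. Among abundant markers, Slc1a3 of astrocytes was at 3989 ± 1100 after PBS and 6263 ± 1466 after IL-33 (adjusted p = 0.2372). Among border-associated macrophage markers 1 of 8 fell, Stab1 (5750 ± 1560 to 2340 ± 284, −1.26, adjusted p = 0.0224), and 0 rose (0 up and 1 down adjusted over the list alone; camera adjusted p = 0.8285). Of 5 tested lymphocyte markers Cd79b rose (493 ± 262 to 3210 ± 1337, 2.75, adjusted p = 0.002966) and Il7r, chosen after its values were seen, fell (1663 ± 361 to 28.4 ± 30.5, −6.41, adjusted p = 0.001303). The counts were 2 up and 2 down adjusted over the list alone, with camera adjusted p = 0.5521. The neutrophil list had 2 tested members, too few for camera, and 0 passed. S100a8 and S100a9, abundant in neutrophils, had 0 reads in all 8 libraries, which allows 3 counts in each by counting error alone.

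Calls differed in how much they depend on single libraries: 386 of the 812 were made in all 8 fits that left out 1 library (247 of the 424 higher, 139 of the 388 lower). In no fit did a called gene change sign, but for the 791 whose groups did not overlap this follows from how they were chosen. The calls of Serpine2, Timp2, Ctsc, Ctsd, H2-DMb1, P2ry6, Srm, Stab1 and, among the largest falls, Kitl were lost when some single library was left out. All of these but Kitl, and also Mmp14, Adamts4, Hexa, C5ar1, Sall1, Mertk, Junb, Rps2, Pfkfb3, Prox1 and Cd79b were lost without the variance trend.

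In the annotation of GRCm38, Il1b (ENSMUSG00000027398) lies on chromosome 2 from 129364570 to 129371139 with 11 distinct annotated exons, P2ry12 on chromosome 3 from 59216272 to 59262871 with 12, Gpr34 on chromosome X from 13632089 to 13640858 with 6, and Mmp14 on chromosome 14 from 54431612 to 54445364 with 22. The 3′ libraries place reads at the end of the last exon, so that the table does not tell isoforms apart. Exons of P2ry12 overlap those of Med12l on the opposite strand, which had a mean of 767 over the 8 libraries.

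The next comparison asked whether the effect of IL-33 differed between females and males, with 2 libraries in each treatment and sex. The 2 male IL-33 libraries are also those with the fewest genes, so that the 2 differences cannot be told apart here. The log2 fold changes of Il1b were 8.90 in females and 8.90 in males, and those of Gpr34 −5.04 and −5.15. All 812 called genes had fold changes of the same sign in both sexes, but for the 791 whose groups did not overlap this follows from how they were chosen. The Pearson r of the fold changes in females and males across the 812 genes was 0.94, where genes are not independent replicates and were chosen on the same libraries. In limma 0 genes passed the threshold for the interaction, with a smallest adjusted p of 0.783, while 809 had an unadjusted p under 0.05. edgeR called 0 genes and DESeq2 441 for the interaction, and without IL-33 replicate 3 limma called 5.

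With 2 against 2 libraries, limma called 135 genes in females (99 higher, 36 lower) and 262 in males (141 higher, 121 lower), 103 of them in both with the same direction; the difference between the sexes is judged by the interaction alone. These counts moved with single libraries. In females they were 2 without IL-33 replicate 1 or 2, 83 without IL-33 replicate 4, 0 without PBS replicate 5 or 6, 25 without PBS replicate 7 and 16 without PBS replicate 8. In males they were 2 without IL-33 replicate 1 or 2, 1052 without IL-33 replicate 3, 15 and 16 without PBS replicates 5 and 6, and 2 without PBS replicate 7. The median SE of the interaction was 0.87 on the log2 scale for genes with a mean of at least 1000, against 0.46 for the treatment effect.

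**Figure D4:**
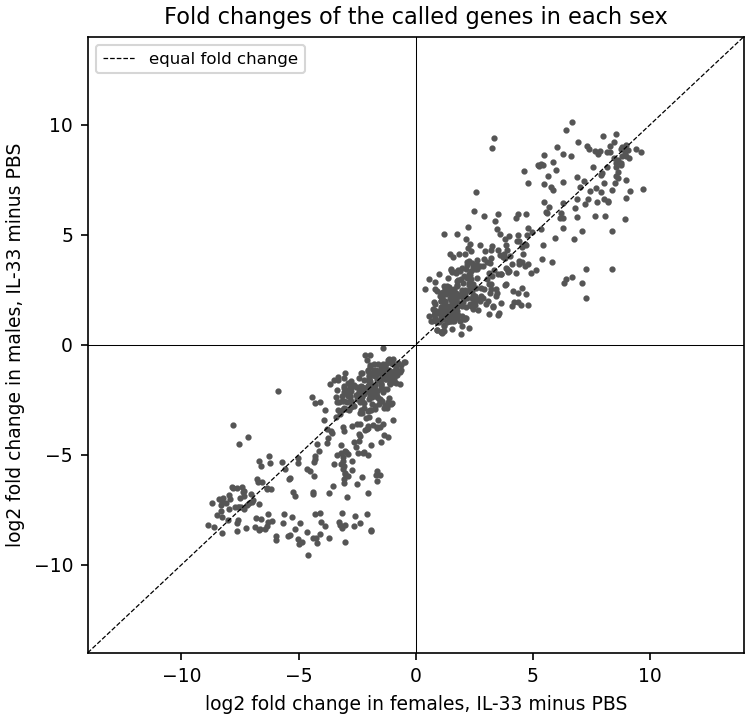
Each point is one of the 812 genes called between IL-33 and PBS, with its log2 fold change in females on the horizontal axis and in males on the vertical axis (2 against 2 libraries in each sex), and a dashed line of equal change. The points lie in the quadrants of equal sign, as the choice of genes without overlap between groups (791 of the 812) brings about, and the Pearson r across these genes is 0.94.

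Males and females were also compared, with treatment in the model, which checks the labelled sex of each library. Xist passed the threshold and was lower in males in all 4 libraries (−8.30, limma adjusted p = 4.39e-06), and was the sole gene to do so; 437 genes had an unadjusted p under 0.05. edgeR called 2 genes and DESeq2 319. The Y-linked gene Ddx3y, chosen after its values were seen, averaged 1455 in the 4 male and 3.73 in the 4 female libraries but did not pass (male minus female 8.38, adjusted p = 0.1715). Each library's Xist and Ddx3y values matched its labelled sex.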

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

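Apart from the gap test, the tests in this part were chosen only after the results were seen. Single libraries were compared with the others of their group by Dixon's gap test, in which chance picks out about 1 in 20 groups: 33 of 304 groups were picked out, where chance gives 15.2.

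Il1rl1 was at 87.9 in IL-33 replicate 4 and at 1 to 1.7 in the other 3, and the low mean after IL-33 rests on those 3. Il1rap had 0 in the same library against 209.9 to 426.3 in the others. Further values of IL-33 replicate 4 far from its group were 186.2 for C3, 32.5 for Ltc4s, 2.9 for Pecam1, 0 for Vcan, 1.9 for Csf3r and 146701 for H2-K1. In IL-33 replicate 3 they were 6647.4 for Junb, 1 for Meg3 and 2 for Slc1a2. In IL-33 replicate 1 they were 174112.4 for Il12b (62048 to 72798 in the others), 19578.6 for Tlr1, 6846.2 for Rps2 and 7167.3 for Glul, and in IL-33 replicate 2 the value was 378.2 for Acod1. Among PBS libraries they were 83 for Gbp2, 109.2 for Cxcl10 and 27.1 for Il6 in replicate 5, and 7160.3 for Sall1 in replicate 6. In PBS replicate 7 they were 76.4 for Cd40, 2191.8 for H2-DMb1 and 209.5 for Ldha, and in PBS replicate 8 they were 169.2 for Dusp1 and 9900.8 for Ctsc. Other values met the gap test but differ from their group by a few reads at most: after IL-33 1 for Marveld2 and 0 for Pik3ip1 in replicate 4 and 2 for Rnase6 in replicate 3, and after PBS 1.7 for Ptges in replicate 6, 0.8 for Vcan and 0 for Lcn2 in replicate 7, and 0.7 for Cx3cl1 and 0 for Mmp25 in replicate 8.

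The count of genes between IL-33 and PBS was set against other splits of the libraries. Of the 35 ways to split the 8 libraries into 4 and 4, 1 gave as many calls as the real one (812), the real split itself. The highest of the others gave 1. Every other split mixes IL-33 and PBS libraries, so that a difference between these groups widens its spread and leaves few calls. The count of splits therefore does not exclude chance by itself, nor another factor shared by the libraries of a group. For males against females 4 of 34 splits gave as many calls as the real one (1) and the highest other gave 5, so that chance is not excluded for that count.

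The 12 largest rises had PBS means of 0.094% to 0.207% of their IL-33 means; they lie close together in part because the largest rises were picked. Reads carried over from other libraries, for example by misassigned indexes, may account for these PBS values: Xist was seen in male libraries at 0.293% of its female mean, and 4 Y-linked genes in female libraries at 0.265% of their male means. Real low expression in PBS microglia cannot be told apart from it, since for 12 of the 12 genes the PBS share lies at or under the Xist share. The same holds for 43 of the 424 rises and 27 of the 388 falls, whose fold changes would then be understated.

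The genes lower after IL-33 were weighed against the smaller number of genes found in IL-33 replicates 3 and 4. These are the 2 male IL-33 libraries, so that a fit without them compares female IL-33 libraries with PBS libraries of both sexes. Without these 2 libraries 473 genes were called lower, more than the 388 reported, which argues against thin libraries as the whole cause. Among genes with a mean under 1000 the fit without them called 165 lower, against 128 reported, of which 92 were the same genes. Uneven capture of molecules in those libraries may still add to single falls.

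Inflammatory genes rose while homeostatic genes fell, which could also arise if the sorted cells were a different mixture. Blood monocytes or neutrophils, many of which the Ly-6C negative gate should already leave out, would bring their abundant transcripts. The 25 fixed markers of these cells with a PBS mean under 10 summed to 0.666% of the Il1b value after IL-33, and 18 of them had no reads there. That percentage is relative to Il1b and does not measure the share of such cells. Some of the 25 had higher means after IL-33 than after PBS. Among them were Vcan (0.21 to 254, limma adjusted p = 0.1458, edgeR adjusted p = 0.04761), Lcn2 (0.61 to 213, limma adjusted p = 0.2269) and Treml4 (0.21 to 51.8, limma adjusted p = 0.3693, chosen after its values were seen). The limit left out 4 markers. Ccr2 (27.0 to 80.3) and S100a4 (37.2 to 140) had higher means after IL-33, and Plac8 (51.0 to 0) and Csf3r (733 to 390) lower. All monocyte markers together took 0.00356% of reads after IL-33 and 0.000841% after PBS (exact permutation p = 0.086). A lower share of microglial RNA would lower all genes that microglia alone express alike. The 100 genes most abundant after PBS had a median log2 fold change of −0.42 (quartiles −1.22 and 0.09). For all tested genes of the fixed homeostatic list it was −1.50. The 100 genes were picked by abundance after PBS alone, which favours genes that fell. Whether other cells express them was not checked, and they include members of the homeostatic list. This comparison therefore cannot decide whether the mixture of cells changed. Within the homeostatic list 27 of 42 tested genes fell, 2 rose and 13 did not pass. Of members chosen after their values were seen, P2ry12 moved by −2.47 ± 0.23 SE, Tmem119 by −0.60 ± 0.18 SE and Cx3cr1 by 0.01 ± 0.16 SE. If microglia alone express these genes, such unlike changes argue against a lower share as the whole cause of the falls in this list. A part played by the mixture stays open. A change of expression within microglia after IL-33 remains as a hypothesis, found and tested on the same data; whether it is a direct response or passes through other cells was not tested.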

How the results depend on the processing

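The tests with a pseudocount of 100, with a minimum mean of 1000, without the 2 libraries with the fewest genes and with a variance trend in camera were chosen after the results were seen; the others were planned. Named genes that were called kept their direction under every setting. For those without overlap between the groups, leaving out libraries could not have reversed it. Of the values of named genes under the alternatives, 2879 kept direction and side of the threshold, 284 lost the call, 39 gained it and 49 changed sign without a call in either; of list values these were 658, 18, 12 and 32. The 812 calls became 501 (204 lower) without a filter, where more genes with few reads are tested, 413 (175 higher, 238 lower) without the variance trend, 1647 (784 higher, 863 lower) with DESeq2 and 377 (228 higher, 149 lower) at an adjusted p under 0.01. For interaction DESeq2 called 441, and for sex it called 319, against 2 with a pseudocount of 100, 8 without the trend and 2 with edgeR. Within females the 135 calls became 264 with a pseudocount of 100, 64 without a filter, 315 at a minimum mean of 1000, 236 with quantile normalization, 232 without the trend, 243 with weights, 375 with edgeR and 1058 with DESeq2. Within males the 262 became 407 with a pseudocount of 100, 146 without a filter, 461 at a minimum mean of 1000, 509 without the trend, 615 with edgeR and 1968 with DESeq2. Leaving out 1 library gave 458 to 963 calls in all, 305 to 432 higher and 153 to 531 lower, 0 to 5 for the interaction, 0 to 131 within females, 2 to 1052 within males and 12 to 14 lists; where 1 library was left in a group, it is assumed to vary like the others. Of the 12 lists called, 6 stayed with an estimated correlation and 7 were called at a minimum mean of 1000. Quantile normalization ended the calls of complement, pattern recognition and ribosomal proteins, and fry those of immediate early genes (adjusted p = 0.0659) and ribosomal proteins (adjusted p = 0.2255). Pattern recognition was also lost without PBS replicate 7 and without the 2 libraries with the fewest genes. Lysosomal genes were called lower with both quantile normalization and fry, neuron and astrocyte markers higher with quantile normalization, and the unfolded protein response higher with fry. Apart from the filter and the smaller groups, the cause was not tested. No paired analysis was possible because the labels number the libraries 1 to 8 and the groups share no number. Recovery in simulated data was 32.4% for a 4-fold change at a PBS mean of at least 1000 and 0.5% below. Genes that did not pass are therefore not shown to be unchanged.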

Other observations

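The read shares below were chosen after the data were seen. The genes called higher took 21.5 ± 2.12% of all reads after IL-33 and 4.72 ± 0.12% after PBS (SD, n = 4 each; exact permutation p = 0.029, the smallest possible), and the genes called lower took 4.50 ± 0.36% and 15.2 ± 0.82% (exact permutation p = 0.029); these genes were chosen on the same libraries. The fixed cytokine and chemokine list took 3.03 ± 0.51% of reads after IL-33 and 0.0636 ± 0.0147% after PBS (exact permutation p = 0.029). The fixed homeostatic list took 5.40 ± 0.27% and 9.35 ± 0.35% (exact permutation p = 0.029).

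Of the 100 genes most abundant after PBS, 5 rose, 34 fell and 61 did not pass. Among the 5 that rose was Mtdh, chosen after its values were seen (42162 ± 7575 after PBS and 148010 ± 34560 after IL-33, log2 fold change 1.80, adjusted p = 2.64e-07). Of the 100 most abundant after IL-33, 43 rose, 5 fell and 52 did not pass. Ranking by the mean of 1 group favours genes that are higher in that group. The opposite counts of the 2 rankings therefore follow in part from the choice of genes. Abundant genes outside the fixed lists that moved, chosen after their values were seen, include Qk, an RNA-binding regulator of splicing (24160 ± 2448 after PBS and 3426 ± 436 after IL-33, log2 fold change −2.82, adjusted p = 5.84e-08), Glul, the glutamine synthetase (24571 ± 1146 and 6130 ± 694, −2.01, adjusted p = 1.34e-06), and Zfhx3, a transcription factor (16732 ± 2313 and 2741 ± 754, −2.65, adjusted p = 2.49e-06). Abundant genes that did not pass, chosen in the same way, include Cst3, cystatin C (371140 after PBS and 292880 after IL-33, −0.36, adjusted p = 0.1245), and Ctss, cathepsin S (225230 after PBS, 224190 after IL-33, −0.01, adjusted p = 0.9756).

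The IL-33 receptor gene Il1rl1 lay between 33.7 and 434.4 in the PBS libraries and at 1, 1.7, 1 and 87.9 in the IL-33 libraries, so that the groups overlap and the direction of a difference is not settled.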
